A study of Homo sapiens with 6 samples.

How the data were processed

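The series measured the genomic positions of FOXN3, a forkhead transcription factor, by CUT&RUN in MRC5, an established human embryonic lung fibroblast line. In CUT&RUN an antibody directs a protein A/G and micrococcal nuclease fusion to its target in permeabilized cells, and the released DNA fragments are sequenced. The labels give 6 libraries: a FOXN3 antibody, an IgG and an input library in each of 2 arms, labelled scr and sh. The labels neither spell out these names nor give the target of the sh arm, so the arms are called by their labels. Peak lists of the 2 FOXN3 antibody libraries were analysed. The IgG and input libraries were not analysed here as libraries of their own.

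The submitters' processing notes name Bowtie2 2.3.4.2, MACS2 and deepTools 2.0.1 and the build GRCh37/hg19. Their options, the MACS2 version and the step each tool was used for are not given in the sources used here. The deposited files are peak lists in the narrowPeak layout, 1 per library. By their names, peaks were called against IgG at a p limit of 0.01, and the lowest −log10 p in them was 2.01. Which arm's IgG library served as control is not given in the sources used here. The deposited fold value of each peak is a linear ratio of the authors' antibody library over its control at the summit. The deposited −log10 columns hold the authors' p-value and q-value of each peak on that scale. The deposited score is another form of the same value, because it equalled the whole part of 10 times −log10 p in 100% of peaks of both lists. The other deposited column used was the summit's distance from the peak start. These are the authors' peak-caller values and were used only to describe, rank or filter peaks within a list. Coordinates are 1-based on GRCh37/hg19.

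The files hold no read totals. The number of antibody-library fragments over each summit (the pileup) and the number expected from the control were therefore recovered from fold and p. The recovery took the fold as (pileup + 1)/(expected + 1) and p as the Poisson tail above the pileup. Whole-number pileups that matched the deposited −log10 p within 0.001 were found for 100% of the peaks of both lists. Expected values sat at a background floor of 0.280 in 53.3% of scr peaks and of 0.232 in 41.9% of sh peaks. A value of 0.456 fragments in the scr list and 0.427 in the sh list, the commonest in a range set after the data had been seen, was taken as the weight of 1 control fragment. Counted over wider windows around the peak, 1 fragment would then weigh 0.139 and 0.0139 in scr and 0.140 and 0.0140 in sh. Of the expected values between the floor and 1 (46.1% of scr and 57.9% of sh peaks), 100% and 99.6% were whole multiples of at least 1 of these 3 weights, within 0.05 of a multiple, against 30.5% and 26.9% of values spread evenly over that range. For the full weight alone these were 24.9% and 43.3%, against 12.7% and 11.2%. On that reading the control libraries held 2.19 and 2.34 times as many fragments as the antibody libraries. With an assumed effective genome size of 2.7 Gb, the antibody libraries are estimated at 2469000 (scr) and 1913000 (sh) fragments. A region is called high-background where the control set an expected pileup over 1.

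Peaks of the lists were called shared where they overlapped by at least 1 bp, and bedtools 2.31.1 gave the same counts, 1075 in both directions. Overlap was set beside 100 random placements of the peaks, with their widths, anywhere on the same chromosome or within 50 kb of their position. Placement anywhere did not avoid assembly gaps, because no hg19 sequence was used here. A further placement, chosen after the data had been seen, was therefore confined to the 88.7% of 100 kb bins of the nuclear chromosomes that held a peak of either list, and to such bins of the other sequences. Also after that, peaks in the 2090 bins of 1 Mb whose 100 kb parts all held a peak were compared by how often sh peaks lay in the bins of scr peaks against any such bin of the chromosome, with an interval from 1000 draws of bins. Overlap by 50% of both peaks used 20 placements. Shares carry exact (Clopper-Pearson) 95% intervals, and a ratio to random placement carries the same bounds divided by the mean of the placements. Ratios between the lists carry intervals from 1000 bootstrap draws. Density was counted by chromosome and in 1 Mb bins of the autosomes. Bins with fewer than 5 peaks over both lists were left out, and the bins used only peaks with an expected pileup of 1 or less. Even placement spread each chromosome's peaks over its bins, 100 times. Chromosome length was taken as the largest mapped position in either list, gaps included, so densities per Mb are low on chromosomes with long gaps in both lists alike. Runs of peaks were formed from peaks of 4 or more fragments outside high-background regions, with gaps of up to 20 kb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

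Each group had 1 library, so differences between the arms have no replicate error and no p-value. Intervals cover counting error only. The comparisons, the thresholds tried (q under 0.05, p of 1e-05 or less), the other overlap rules and the rule for named regions were set before the data were examined. That rule took regions on assembled nuclear chromosomes with q under 0.05 by −log10 p. It named the 10 highest scr peaks that overlapped a sh peak, the 10 highest scr peaks that overlapped none and the 10 highest sh peaks that overlapped no scr peak. It also named the 5 peaks of highest fold in each list wherever they lay. The recovered fragment numbers, the high-background class, the 1 Mb bins, the removal of chromosome means from them and the runs were chosen after the data had been seen.

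On simulated data, all 1000 pileups of 2 to 5 fragments (100%) were recovered exactly. Their fold and p were made with the formulas that the recovery assumes, so this checks the calculation and not those formulas. With 1000 shared peaks planted among 54403, the overlap above random placement was 991.8 peaks. With none planted, the ratio of observed to placed overlap averaged 0.997 over 20 simulated pairs of lists (0.950 to 1.08). Both simulated lists were placed at random anywhere on their chromosomes, as in the placement they were set beside. A ratio near 1 was therefore built in and checks the calculation only. Its range is no baseline for the real lists, whose peaks avoid gaps and vary in density. Shares by gene annotation, gene lists, sequence motifs and the FOXN3 locus were planned but not analysed here, because no hg19 genome or annotation was used here. Regions are named by coordinates for the same reason.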

Results

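FOXN3 CUT&RUN peaks were compared between 2 arms of MRC5 lung fibroblasts, labelled scr and sh, with 1 FOXN3 antibody library per arm. The series title concerns the conversion of fibroblasts into cancer-associated fibroblasts by exosomes of A549, a human lung adenocarcinoma line. The scr list held 54403 peaks and the sh list 55180. Their median widths were 384 bp (quartiles 339 and 462) and 397 bp (quartiles 357 and 460), and they covered 23.4 Mb and 24.3 Mb. With 1 library per arm there was no replicate spread to set the differences against, so no p-value between the arms is given. Intervals cover counting error only, and fold, p and q are the authors' values for each peak.

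The first comparison asked how many sites each library held and how strong they were. Peak numbers were close in the whole lists, but the scr library held more of the stronger peaks. The scr library was also estimated to be the larger, at 2469000 against 1913000 fragments, and a larger library puts more fragments over a summit. Numbers were not adjusted for depth, so the excess of stronger scr peaks cannot be told apart from unequal depth. At q under 0.05 the scr list kept 616 peaks (1.13%) and the sh list 250 (0.453%). Peaks with 5 or more fragments at the summit numbered 1377 in scr and 590 in sh. In both lists most peaks rested on very few fragments. Peaks of 2 fragments made up 43.5% of the scr list and 56.1% of the sh list, and peaks of 2 or 3 fragments 86.5% and 93.0%. Over 1 control fragment (an expected pileup of 0.456 in scr and 0.427 in sh), 2 fragments passed the p limit of 0.01 only in sh. Numbers of peaks of 2 fragments, and with them the lengths of the whole lists, are therefore not like for like. How many sh peaks this step added was not counted. The median fold over control was 2.75 in scr and 2.44 in sh. The order of the arms depended on the threshold: at p of 1e-05 or less the sh list had more peaks, 1839 against 951. Over the commonest expected pileup (0.280 in scr and 0.232 in sh), 4 fragments gave a −log10 p of 4.95 in scr and 5.34 in sh, so 4 fragments passed that limit only in sh.

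**Figure D1:**
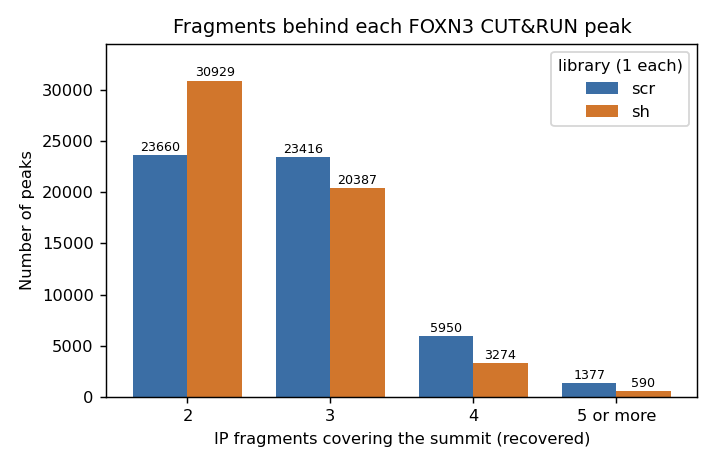
Number of peaks (vertical axis) by the number of antibody-library fragments over the summit (horizontal axis), for the scr and sh lists, 1 library each. The sh list had more peaks of 2 fragments (30929 against 23660), and the scr list more at 3, 4, and 5 or more fragments. Numbers at 2 fragments are not like for like, because over 1 control fragment 2 fragments passed the p limit of 0.01 only in sh.

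The second comparison asked which sites the arms shared. Few peaks were found in both: 1075 scr peaks overlapped a sh peak, 1.98% of the list (95% interval 1.86 to 2.10). Random placement anywhere on the chromosome gave 1.63% (range of 100 placements 1.49 to 1.75), so the observed overlap was 1.21 times that (1.14 to 1.29). Placement within 50 kb gave 1.81%, a ratio of 1.09 (1.03 to 1.16), and placement confined to 100 kb bins that held a peak gave 1.82%, a ratio of 1.08 (1.02 to 1.15). For the sh list the share was 1.95% and the ratios 1.21 and 1.10. Overlap was higher among the top peaks by −log10 p. Of the top 500, 7.60% of scr peaks and 6.60% of sh peaks were shared, against 2.52% and 2.26% under placement within 50 kb. Of the top 10000, 2.31% and 2.09% were shared, against 1.93% and 1.81%. Among peaks with q under 0.05 outside regions where the control was high, the ratio was 1.59 (0.949 to 2.49) in scr and 1.97 (0.911 to 3.68) in sh, and both intervals included 1. As much overlap came from 3 of 100 placements in each list, so a small excess among these peaks is neither shown nor excluded.

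**Figure D2:**
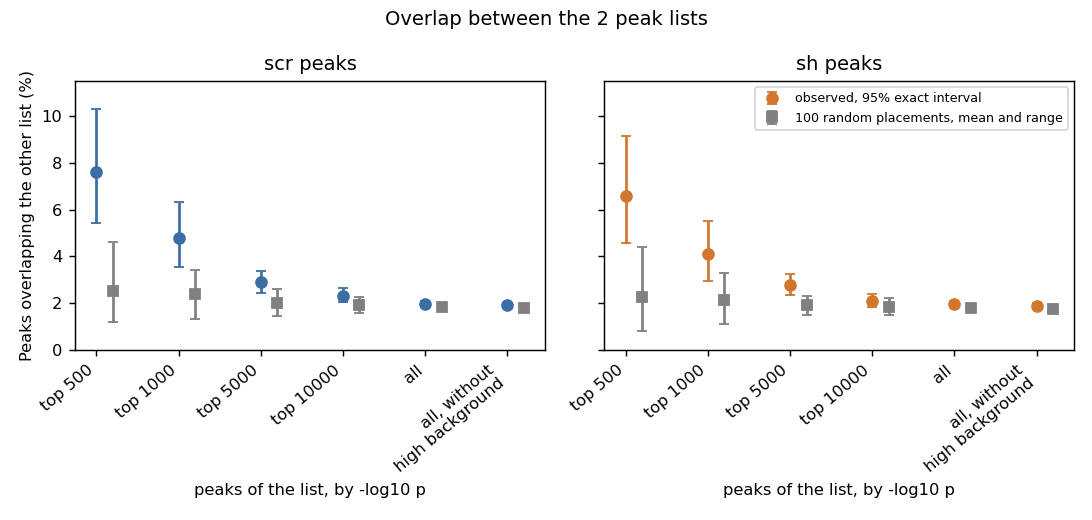
Percent of scr peaks (left) and sh peaks (right) that overlap the other list, by rank on −log10 p. Coloured circles are observed shares with exact 95% intervals, and grey squares are the mean and range of 100 random placements within 50 kb. Shares fall from 7.60% and 6.60% in the top 500 to 1.98% and 1.95% in the whole lists.

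Ranked by −log10 p, the first shared regions lay where the control itself was high. All 10 shared regions named by the rule were high-background. The first was chr8:43092858–43093228, beside the centromere, with 1887 scr fragments over an expected 931.5 and a fold of 2.02 in scr and 2.95 in sh. Next were chr8:43094747–43095305 (fold 2.31 in scr, 3.39 in sh) and chr22:18883632–18884066 (3.75 in scr, 3.01 in sh). Others lay at chr18:18518768–18519642, with a scr fold of 1.51, and chr19:27731954–27732318, with a scr fold of 1.32, both also beside a centromere. High-background regions were 0.623% of the scr list and 0.274% of the sh list. Of them, 43 of 339 scr peaks (12.7%, 9.33 to 16.7) and 41 of 151 sh peaks (27.2%, 20.2 to 35.0) were shared. The 37 shared scr peaks among them on nuclear chromosomes fell into 19 loci on 12 chromosomes. Of 17 overlaps between peaks with q under 0.05 in both lists, 16 were high-background. The other was chr17:4126172–4127001, with 12 fragments and a fold of 9.16 in scr, which overlapped a sh peak of 5 fragments and a fold of 4.87. It was singled out after its values were seen. Without high-background regions, 1029 scr peaks overlapped a sh peak, and the ratio to placement within 50 kb was 1.06 (0.998 to 1.13).

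Peaks of 5 or more fragments made up 6.88% of shared against 2.44% of scr-only peaks, and 5.30% against 0.985% in the sh list. Without high-background regions these shares were 2.92% and 1.93% in scr, and 1.46% and 0.789% in sh. They rest on 30 and 15 shared peaks, and the ratios of such overlap to placement within 50 kb, 1.39 (0.940 to 1.97) and 1.74 (0.979 to 2.84), had intervals that included 1. As much overlap came from 5 of 100 placements in scr and 2 of 100 in sh. The median fold was 2.75 for shared and for scr-only peaks, and 2.44 for shared and for sh-only peaks. It can take few values, because most peaks have 2 or 3 fragments.

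Among regions found in the scr list alone, the highest fold was 16.5 at chr6:74229771–74231611, a peak of 1841 bp with 23 fragments at the summit. It was followed by chr2:128999222–128999759 (fold 11.7, 14 fragments), chr7:103845511–103845818 (fold 10.2, 12 fragments), and chr1:216545630–216546136 and chr2:210228233–210228875 (both fold 9.62 with 13 fragments). The other 8 of the 10 scr-only regions of highest −log10 p were high-background. They included chr17:22020540–22020919, with 446 fragments and a fold of 5.35. They also included chr1:565579–566726, in a known nuclear copy of mitochondrial DNA, with 442 fragments and a fold of 2.93. Also among the 8 were chr2:92296666–92296984 and chr22:18717935–18718268. These lay within loci that also held shared high-background peaks (chr2:92290591–92316390 and chr22:18688046–18884066).

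Among regions found in the sh list alone, the highest folds on nuclear chromosomes were at chr2:234668908–234669871 (fold 15.4, 21 fragments), chr10:101610223–101610595 (fold 13.8, 16 fragments) and chr20:4004364–4005359 (fold 12.99, 15 fragments). Also named were chr10:101563647–101564127 (fold 9.84, 12 fragments), chr1:60399796–60400712 (fold 8.09, 14 fragments), and chr10:101589972–101590351 and chr12:21325524–21325930 (both fold 8.12 with 9 fragments). The remaining 3 of the 10 sh-only regions were high-background: chr10:42391472–42391832, chr10:42599675–42600278 and chr2:92295798–92296321. The first and last of these lay within loci that also held shared high-background peaks (chr10:42364736–42535018 and chr2:92290591–92316390). Their absence from the scr list is therefore one of peak position, not of the locus.

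Of these sh-only regions, 3 belonged to 1 stretch, chr10:101542377–101610595, which was examined after its peaks had been seen. Over 68.2 kb it held a run of 14 sh peaks with 5 to 16 fragments, 13 of them with q under 0.05. The scr list had 3 peaks of 2 fragments each there. The 16 sh peaks of the stretch, of any strength, covered 13.3% of it. Runs of 3 or more peaks numbered 61 among the 6963 scr peaks used and 11 among the 3691 sh peaks, where random placement anywhere gave 17.6 (8 to 28) and 2.48 (0 to 6). The next longest sh runs were chr12:21007740–21036599 (5 peaks) and, with 4 peaks each, chr12:21325524–21332244 (up to 9 fragments), chr1:145053612–145091905 (up to 6) and chr21:10472021–10502896 (up to 5). The sh-only region of highest fold lay in a run of 3 at chr2:234668908–234681345. In the scr list the longest run was 8 peaks of 4 to 6 fragments at chrX:114960828–115001178, where the sh list had 0 peaks.

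**Figure D3:**
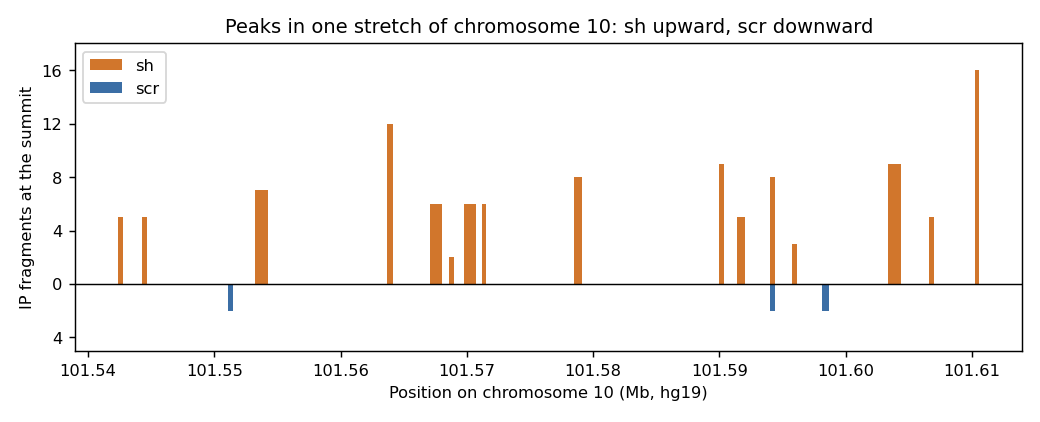
Antibody-library fragments at the summit (vertical axis) of each peak along chr10:101542377–101610595 (horizontal axis, Mb, hg19), with sh peaks drawn upward and scr peaks downward at their true widths. The 16 sh peaks reach 16 fragments, and the 3 scr peaks have 2 fragments each.

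The third comparison asked how peaks were spread over the chromosomes. The scr list was denser than the sh list on chromosomes 16, 17, 19 and 22, which are known to be gene-dense and rich in G and C. Peaks per Mb were 21.97 and 19.8 on chromosome 16, 27.0 and 21.6 on chromosome 17, 27.6 and 22.04 on chromosome 19, and 20.9 and 15.1 on chromosome 22, in scr and sh. The 4 chromosomes, grouped after their densities were seen, held 1.24 times as large a share of the scr as of the sh list (1.203 to 1.288). Among peaks of 5 or more fragments the ratio was 1.32 (1.06 to 1.70), but for chromosome 22 alone it fell below 1, to 0.651 (0.382 to 1.14). Chromosome 11, outside that group, gave 1.11 (1.05 to 1.17), close to chromosome 16 at 1.13 (1.05 to 1.201). Ratios under 1 with intervals that excluded 1 were also found on chromosomes 2 (0.953), 5 (0.932), 6 (0.913) and 12 (0.949). These intervals treat peaks as independent. Counts of scr peaks varied more than that between 1 Mb bins (variance over mean 2.75 within chromosomes), so the intervals are too narrow. No allowance was made for the number of chromosomes compared, so bounds close to 1 do not settle a difference. On the gene-poor chromosomes 4 and 13 the scr list was the sparser, with 15.6 against 18.5 and 13.2 against 15.4 peaks per Mb. Among peaks of 5 or more fragments the ratios there were 0.935 (0.635 to 1.45) and 0.622 (0.285 to 1.39), and both intervals included 1. Together with chromosome 6, grouped after their densities were seen, they gave 0.881 (0.856 to 0.908) in the whole lists and 1.12 (0.836 to 1.51) at 5 or more fragments, where chromosome 6 alone gave 2.07 (1.21 to 4.01).

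**Figure D4:**
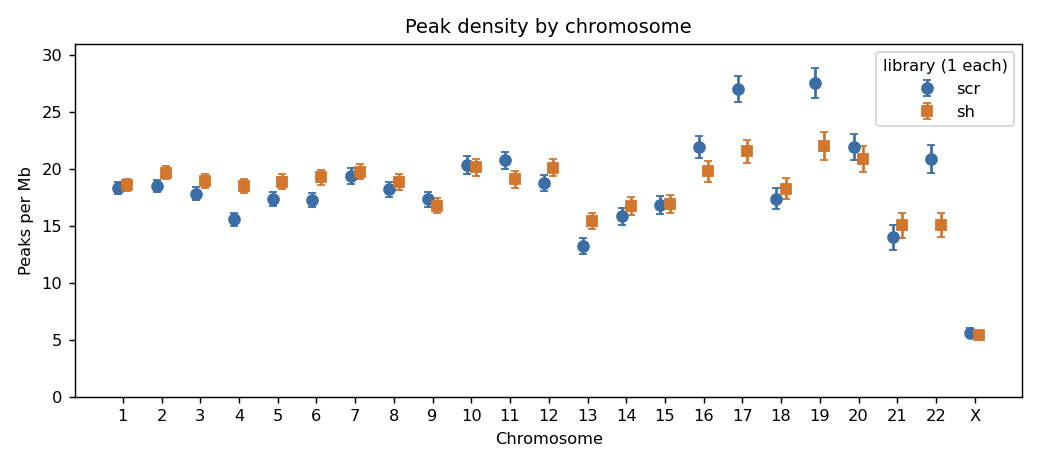
Peaks per Mb (vertical axis) on each chromosome (horizontal axis) for the scr and sh lists, 1 library each. Bars are 95% counting intervals (normal approximation), and among others scr lies above sh on chromosomes 11, 16, 17, 19 and 22 and below it on chromosomes 2, 4, 5, 6, 12 and 13.

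The scr list was also the more uneven within chromosomes. Over 2705 autosomal bins of 1 Mb, scr peaks averaged 19.5 per bin (SD 7.86 over bins) and sh peaks 19.9 (SD 4.91). The variance over the mean was 3.17 in scr and 1.21 in sh, where even placement within each chromosome gave 1.35 to 1.51 and 0.973 to 1.11. With each chromosome's own mean removed it was 2.75 in scr and 1.17 in sh, where the same placement gave 0.915 to 1.08 and 0.928 to 1.06. The densest scr bins were chr16:1000001–2000000, with 57 scr and 22 sh peaks, and chr14:105000001–106000000, with 55 and 34. The densest sh bin was chr12:21000001–22000000, with 38 sh and 13 scr peaks, and it contains both chromosome 12 runs. Spearman's rho between the lists over bins was 0.32, where bins are not independent replicates.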

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

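These results come from sequences outside the assembled nuclear chromosomes and are given because their signal lay above the control. Peaks on such sequences entered the counts and overlaps of whole lists and of their subsets by q, p, rank, fragment number or background. The results below were chosen after the peaks had been seen, and no explanation for them was tested. In the sh list the 2 peaks of highest −log10 p were chrUn_gl000220:110514–110955, with a fold of 11.0 and 779 fragments, and chrUn_gl000220:154486–154930, with a fold of 11.2 and 768 fragments. They start 43972 bp apart on a sequence known to carry ribosomal RNA gene repeats. The scr list had 12 peaks on that sequence, with a highest fold of 3.20, and the sh list 3. In the scr list a single peak, chrM:103–16511, took in nearly the whole mitochondrial sequence, with a fold of 2.38 and 2447 fragments at the summit, and the sh list had 0 peaks there. By −log10 p, though not by fold, the strongest scr peak on an unplaced sequence was chrUn_gl000212:40516–41136, with a fold of 2.28. It overlapped a sh peak with a fold of 1.57. In all, 138 scr peaks and 92 sh peaks lay on unplaced or random sequences.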

How the results depend on the processing

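The settings based on fragment number, on leaving out high-background regions and on bins that hold a peak were chosen after seeing the data. The sh list was slightly the longer (log2 ratio sh over scr 0.02), and this reversed to -1.30 at q under 0.05 (616 scr and 250 sh peaks), -0.92 at 4 or more fragments (7327 and 3864) and -1.22 at 5 or more (1377 and 590). At p of 1e-05 or less it was 0.95 (951 and 1839), where 1222 sh peaks of 4 fragments over the commonest expected pileup passed and scr peaks of that kind did not. The lengths of the whole lists are not like for like, because over 1 control fragment 2 fragments passed the p limit of 0.01 only in sh. The shared share of the scr list was 0.831% with overlap of 50% of both peaks, 0.939% with summits within 200 bp, 2.76% at q under 0.05 in both lists and 4.94% for peaks at p of 1e-05 or less against the whole sh list. The sh shares were 0.819%, 0.926%, 6.80% and 3.43%, and 0.979% at that p in both lists. Stricter overlap rules lower these shares by construction. A shorter other list does so too, so the rise at q under 0.05 is not of that kind: 16 of its 17 overlaps were high-background. The scr ratio to random placement stayed above 1: 1.09 within 50 kb, 1.08 in 100 kb bins that hold a peak, 1.303 at 50% of both peaks, 100 at q under 0.05 in both lists, 29.5 at p of 1e-05 or less in both lists, 2.81 against the whole list, and 1.06 both within 50 kb and in such bins without high-background regions, where the intervals included 1. Chromosomes 16, 17, 19 and 22 kept a scr to sh ratio over 1, at 1.89 for p of 1e-05 or less, 1.37 for 4 or more and 1.32 for 5 or more fragments, but chromosome 22 alone reversed to 0.651 at 5 or more. Chromosomes 4, 13 and 6, grouped after the data were seen, moved from 0.881 to 0.739 at p of 1e-05 or less and reversed to 1.12 at 5 or more fragments, where chromosome 6 alone reversed to 2.07. At p of 1e-05 or less chromosome 13 alone gave 0.257 (0.0946 to 0.481), from 8 scr and 62 sh peaks, and chromosomes 4 and 6 gave 0.844 and 0.925. At p of 1e-05 or less the lists hold unlike peaks, because 1222 of the 1839 sh peaks had 4 fragments over the commonest expected pileup and no scr peak did. The ratios at that p are therefore no like-for-like check. The cause of these shifts was not tested. The variance over mean per bin was 1.91 in scr and 1.22 in sh at 4 or more fragments, where bins hold fewer peaks, so the lists lay closer together there. Leaving aside the median fold, which can take few values, 50 values moved, 6 reversed and 26 stayed within the interval of the value reported (for variance over mean, within the width of the range under even placement; merging left peak numbers unchanged), including the shares over nuclear chromosomes alone and over equal list lengths. Annotation shares, gene lists and motifs were not run, and no library could be left out with 1 per group. No paired analysis was possible because each arm had 1 FOXN3 antibody library. Depth, with most peaks resting on 2 or 3 fragments and the scr library estimated to be the larger, and the single library per arm both limit these results.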

Other observations

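The tests of overlap and of copies in the control were chosen after their results were seen, as was the look at chromosome ends. The other tests below were set before theirs. Peaks of the scr list were denser near the ends of the autosomes. With length counted as 100 kb bins that hold a peak, the last 5 Mb by coordinate held 29.1 scr peaks per Mb against 19.8 elsewhere, a ratio of 1.47 (1.42 to 1.53). For sh they held 21.9 against 20.5, a ratio of 1.07 (1.03 to 1.11). The first 5 Mb, which held peaks on 17 autosomes, gave 1.37 (1.305 to 1.42) for scr and 1.09 (1.04 to 1.14) for sh over what lay in neither end.

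The lists overlapped more often than random placement anywhere gave. High control background contributes, because high-background peaks were shared 4.15 times (scr) and 7.52 times (sh) as often as placement within 50 kb gave. With such regions left out of both lists, the scr ratio was 1.17 (1.10 to 1.25) over placement anywhere and 1.06 (0.995 to 1.12) over placement in bins that hold a peak. Those bins were set by the peaks of these same lists, so a lower ratio there was built in. Random placement into stretches that hold no peaks lowers the placed overlap, but whether these stretches are assembly gaps was not tested. Peaks of both lists lying in the same broad parts of the chromosomes add a little, because in 1 Mb bins whose 100 kb parts all held a peak, sh peaks were 1.02 times (1.01 to 1.02, bins redrawn) as frequent in the bins of scr peaks as in any such bin of the chromosome. Within 50 kb the ratio was 1.06 in both lists (scr 0.998 to 1.13, sh 1.00 to 1.13), and as much overlap came from 2 of 100 placements for scr and 0 of 100 for sh, so a small set of FOXN3 sites common to both arms cannot be told apart at this depth from background below the limit used.

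The scr peaks were denser than the sh peaks on chromosomes 16, 17, 19 and 22 and more uneven between 1 Mb bins. If local background set by the control library were the cause, peaks of 5 or more fragments outside high-background regions, which pass the caller's limit at any such background, would give a ratio near 1, and it was 1.29 (1.01 to 1.73). Its lower bound is close to 1, chromosome 22 alone gave 0.616 (0.324 to 1.33), and chromosomes 4, 13 and 6, sparser in the whole scr list, gave 1.05 (0.773 to 1.43), so this test is a weak one and local background may still be part of the cause. At 4 or more fragments, high-background regions included, the ratio for the 4 chromosomes was 1.37 (1.245 to 1.513). Chromosome 22 alone then gave 1.12 (0.853 to 1.48), and chromosomes 4, 13 and 6 gave 0.897 (0.815 to 1.00). That setting was not part of the test. More fragments per peak in scr is not enough either, because with both lists thinned to the same number of peaks per fragment class the scr variance over mean was 2.66 to 2.77 and the sh value 1.17 to 1.22. Unequal yield of DNA rich in G and C, different background cleavage of open chromatin and a difference between the arms in FOXN3 binding could each give this pattern and were not tested.

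The run of strong sh peaks on chr10:101542377–101610595 stood apart from chance clustering of peaks, since 0 of 100 random placements held a run as long and the longest had 4 peaks against 14. Clustering beyond placement was not confined to this run, since the longest scr run had 8 peaks against 6 in 100 placements, but the sh run of 3 on chromosome 2 was no longer than placement gave. Placement compared run length only, so the strength of that run of 3, up to 21 fragments, was not tested. It also stood apart from even gain of the whole stretch: fragments laid evenly reached 16 at a summit while covering as little as 13.3% of the stretch in 0 of 1000 simulations at each total tried. Extra copies present alike in the antibody and the control library are argued against by the control, whose expected pileup summed to 4.55 (upper bound 8.21) over the 14 peaks against 107 antibody-library fragments, where the caller's p limit alone would have let it reach 47.2 and 0 peaks of the run had been left out for high background. Which arm's IgG library gave that control is not known here. If it was the scr one, it cannot exclude DNA present in all sh libraries. What stays open is DNA made of separate pieces of this stretch, in the antibody library alone or, in that case, in all sh libraries. FOXN3 binding in the sh arm at many sites of the stretch stays open too. Either may apply to the shorter runs on chromosomes 2 and 12 and to other sh-only regions. Neither was tested, because no hg19 annotation was used here and the IgG and input libraries were not analysed here.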
